A study of Mus musculus with 24 samples.

How the data were processed

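The samples were left quadriceps muscles of WT and Lama2-CMD mice on the backgrounds B6, 67, 87 and D2, snap frozen at 25 weeks, with 3 mice per group and 24 libraries. Per the labels, total RNA was extracted with TRIzol, libraries were made with a stranded mRNA kit and sequenced on a NextSeq 2000 as paired reads of 58 bases, and reads were aligned to GRCm39 (mm39). The aligner and the counting program are not given in the sources used here. The files deposited by the authors hold raw counts per Ensembl gene, as unique exon reads and as total exon reads, which also hold reads that match more than 1 place. They also hold RPKM, deposited by the authors as reads scaled by exon length and by a library total larger than the sum of exon reads. They hold TPM, deposited by the authors as transcripts scaled by exon length so that each library has the same sum. RPKM and TPM were not used in any test.

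Total exon reads were analysed. They ran from 32292613 to 51715975 per library, 97.7% to 98.2% of them unique. Each file lists 25369 genes, of which 21643 are protein-coding and 6830 had 0 reads in all libraries. Genes with too few reads were removed with filterByExpr by group (minimum count 10, minimum total count 15), which left 14789. Counts were fitted in edgeR 4.0.16 (R 4.3.3) with glmQLFit on TMM-normalised libraries, with a term for each of the 8 groups and a term for sex as labelled. The mean prior degrees of freedom were 3.88. CPM are reads scaled by the TMM-adjusted library size. Within each strain CMD was compared with WT by glmQLFTest. Differences between strains in the CMD effect were tested as interactions, by an F test over the 4 strains and for each pair, and WT groups were compared by an F test and for D2 against B6. P-values were adjusted by the Benjamini-Hochberg method and the threshold was 0.05. They measure the spread between these samples. Libraries of different groups share no number, so nothing was paired.

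Gene lists were written before the data were examined, as were the comparisons and a first set of alternatives. There were 26 lists with 417 genes, of which 2 were not found, and 3 were matched by gene ID because the files add a copy number to the symbol. Lists were tested with fry (limma 3.58.1), adjusted over 104 tests for the strain effects and 156 for the differences. Fry asks whether the genes of a list move one way on balance and does not compare them with other genes. Camera with an estimated correlation between genes makes that comparison. The 24 neuronal and 22 sarcomere genes of the closing tests were listed after results were seen. Counts of list genes use the adjustment over all genes, with the adjustment over the list alone beside them. Of all tested genes 18.0% were called in B6, 24.4% in 67, 24.0% in 87 and 25.4% in D2, raised and lowered together. A list can pass in fry with a share of called genes no higher than these.

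Genes were named by rule. In each strain these were Lama2, the 4 most raised and 4 most lowered genes past the threshold with a mean log2 CPM of at least 1 and all 3 CMD libraries on one side of all 3 WT libraries, and the gene of each list past the threshold with the largest change. Genes without a symbol, genes with a symbol that starts with Gm or a digit or ends in Rik, and H2 and immunoglobulin genes were left out of the most raised and lowered. Shared genes were the 5 raised and 5 lowered in all strains whose smallest change was largest. For the F test the 12 smallest p were named, and for D2 against B6 the 6 raised and 6 lowered with the smallest p, both for the CMD effect and for WT. Ltbp4, Anxa6, Spp1, Lama1, Lama4 and Lama5 were read in every strain. Not every gene that the rule names is reported here. A few further values of single genes and libraries are given to describe libraries 16 and 23 and WT levels. Where a group had 0 reads a fold was given as a lower bound from 3 reads over the group, and with 1 to 3 reads as a ratio with a 95% interval. These bounds and intervals cover counting error only.

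Alternatives set before the data were examined were no sex term, no filter, only the libraries compared, the 15 females as labelled, RLE size factors, each library left out in turn, the DESeq2 1.42.0 test, camera, and a log2 fold change of at least 1 beside the threshold. Alternatives added afterwards were sex from Y-linked reads (male above 5 CPM over 4 genes), unique reads only, libraries 16 and 23 left out together, and the last with sex from Y-linked reads. The method was tested on simulated data made from these libraries with 14554 genes. Of genes changed 2-fold, 54% to 61% were recovered in a strain, and of genes changed 4-fold 90% to 92%. For differences between strains by the F test these were 16% and 83%. At most 5.23% of calls in the simulation were false. Its genes were drawn independently, with no sex effect, no wrong sex label and no deviant library. The false share among the real calls can therefore differ. Chromosome and neighbour order came from GENCODE M21 on GRCm38, where 25265 of the gene IDs were found. Loading and figures used Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.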

Results

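The data are transcript counts from the left quadriceps muscle of mice aged 25 weeks. Each mouse was either wild type (WT) or carried the Lama2-CMD mutation, a model of congenital muscular dystrophy caused by loss of the laminin alpha chain of the muscle basement membrane. There were 4 genetic backgrounds: B6 (C57BL/6J), D2 (DBA/2J), and the strains that the labels call 67 and 87, which the study design names BXD-67 and BXD-87. BXD strains are inbred mosaics of the B6 and D2 genomes. Each of the 8 groups held 3 libraries, numbered 1 to 24 in the order B6 WT, B6 CMD, 67 WT, 67 CMD, 87 WT, 87 CMD, D2 WT and D2 CMD. Total exon reads per library ran from 32292613 to 51715975. Between 15477 and 16405 genes were detected per library.

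Reads of 4 Y-linked genes were compared with the sex label of each library. In 20 libraries they matched the label, and in 4 D2 libraries they went against it. D2 WT libraries 19 and 21 are labelled male and held 1 and 0 Y-linked reads. D2 CMD libraries 22 and 24 are labelled female and held 4927 and 4858. Sex as labelled was a term of every model unless stated. The main D2 results and the differences that involve D2 therefore use a sex term that the reads contradict in those 4 libraries. Lists that passed in D2 are given below also with the sex that the Y-linked reads show. Single D2 genes are given so where that ends a call. Both codings leave the D2 comparison leaning on few libraries, since by the label 1 of 3 WT and 3 of 3 CMD libraries are female, and by the Y-linked reads 3 of 3 WT and 1 of 3 CMD libraries are female.

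**Figure D1:**
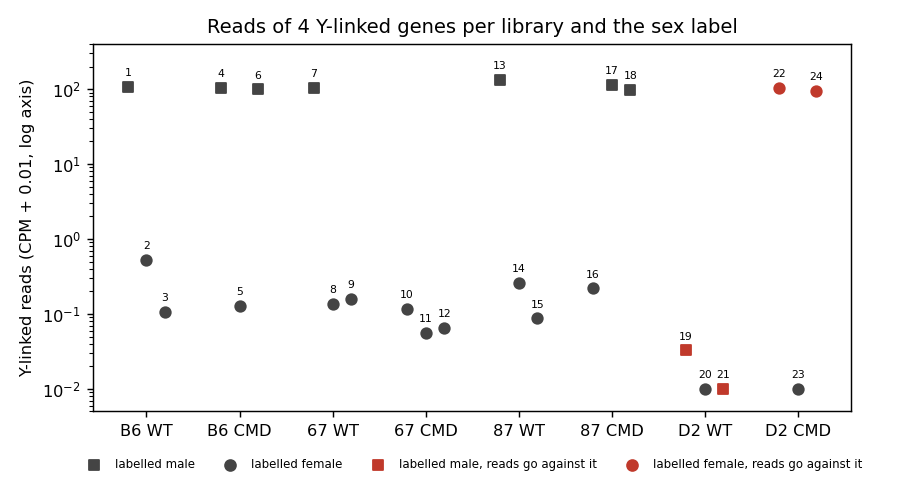
Reads of 4 Y-linked genes in each of the 24 libraries, in CPM (reads scaled to a common library size) plus 0.01 on a log axis, with squares for libraries labelled male, circles for libraries labelled female and red for reads that go against the label. Libraries 19, 21, 22 and 24, all D2, go against their labels.

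On the first principal component (28% of the variance) the CMD libraries of each strain lay above its WT libraries, and the second (18.5%) set all 6 D2 libraries apart, WT at 54.8 to 62.1 and CMD at 30.5 to 45.3, where the highest of the others was 15.6. Replicates of a group correlated with a mean Pearson r of 0.945 to 0.984 across genes. The lowest was 87 CMD library 16. That library held 1180 CPM of the metallothionein transcript Mt1 and 3815 CPM of the ubiquitin ligase transcript Trim63, against 20.1 and 27.3 CPM of Mt1 and 215 and 290 CPM of Trim63 in 87 CMD libraries 17 and 18.

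**Figure D2:**
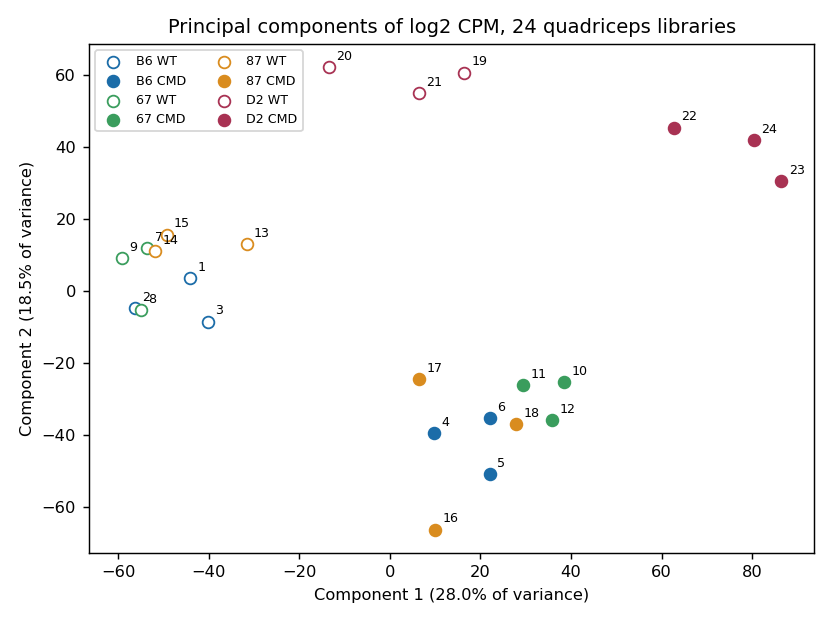
The first and second principal components of log2 CPM in the 24 quadriceps libraries, with open circles for WT, filled circles for CMD and library numbers beside the points. The 3 D2 WT libraries lie between 54.8 and 62.1 on the second component.

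Lama2 (ENSMUSG00000019899) is the mutated gene, and its allele is not given in the labels. Its transcript level fell in CMD muscle of B6 and of 87 and passed no test in 67 or D2. In B6 it went from 42.6 ± 7.07 CPM in WT to 21.2 ± 4.49 in CMD (mean ± SD, n = 3 each), a log2 fold change of -1.16 ± 0.20 (SE, adjusted p = 0.00115). In 87 it went from 30.2 ± 4.78 to 16.3 ± 3.29 CPM (-1.02 ± 0.19, adjusted p = 0.00121). In 67 it was 26.9 ± 2.29 in WT and 27.8 ± 7.06 in CMD (0.16 ± 0.19, adjusted p = 0.557), and in D2 35.0 ± 9.84 and 27.0 ± 3.26 (-0.09 ± 0.20, adjusted p = 0.761). The D2 value with sex from the Y-linked reads was -0.58 (adjusted p = 0.079). The effect differed among the 4 strains (F test of the interaction, adjusted p = 0.0119), but not past the threshold without a sex term (adjusted p = 0.119). In 67 and D2 the Lama2 level by itself did not tell CMD from WT.

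**Figure D3:**
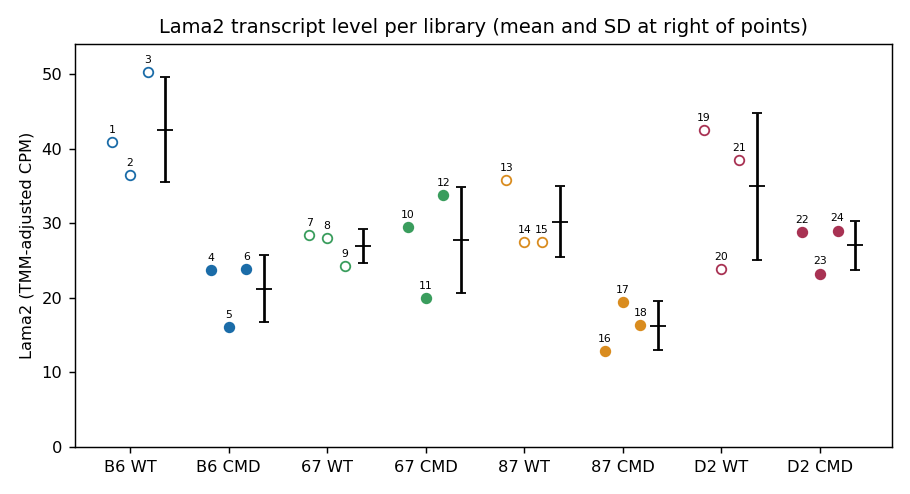
Lama2 transcript level in CPM adjusted by TMM for each library, grouped by background and genotype, with the mean and SD of each group at the right of its points. Means run from 16.3 (87 CMD) to 42.6 (B6 WT).

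Other laminins and known dystrophy modifiers were read in every strain. Spp1, which encodes osteopontin, rose in CMD in all 4 strains, with log2 fold changes of 2.74 in B6, 4.28 in 67, 2.49 in 87 and 1.90 in D2 (adjusted p = 0.00476, 0.000224, 0.00610 and 0.0258). In D2 the Spp1 change was 1.10 with adjusted p = 0.185 without libraries 16 and 23. Lama4 rose in 67 (0.76, adjusted p = 0.0141) and in D2 (0.66, adjusted p = 0.0357), and its D2 value with sex from the Y-linked reads was 0.05 (adjusted p = 0.920). Ltbp4, Anxa6 and Lama5 passed the threshold in no strain. Lama1 had 2 to 22 reads per group and was not tested.

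Whether backgrounds share a response was asked from the genes changed the same way in all 4 strains. There were 383 such genes, 190 raised and 193 lowered in CMD, where 3.10 and 1.90 would be shared by lists drawn independently. The raised genes included the fusion factors of muscle progenitors Mymk and Mymx, Sln, which encodes an inhibitor of the sarcoplasmic calcium pump, Krt18, a keratin, and Th, tyrosine hydroxylase. Sln (ENSMUSG00000042045) rose by log2 fold changes of 6.35 in B6, 9.39 in 67, 10.06 in 87 and 6.19 in D2. Mymk (ENSMUSG00000009214) rose by 6.59, 5.89, 5.18 and 6.64, and Krt18 (ENSMUSG00000023043) by 5.58, 6.12, 7.16 and 7.16, in the same order. Th (ENSMUSG00000000214) had 0 reads in every WT group and 160, 27 and 345 reads in B6, 67 and D2 CMD, at least 48.8-fold, 9.28-fold and 112-fold higher with a floor of 3 reads over the WT group, and was at least 34.7-fold higher in 87 CMD. Mymx (ENSMUSG00000079471) had 1 read in B6 WT and 262 in B6 CMD, a ratio of 240 with a 95% counting interval of 42.7 to 9513. In 67 it had 3 and 726 reads, a ratio of 250 (85.1 to 1213), and its log2 fold changes in 87 and D2 were 6.31 and 5.83.

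The genes lowered in all 4 strains included Dkk3, a secreted regulator of Wnt signalling, Prima1, which anchors acetylcholinesterase to the membrane, Kl, which encodes klotho, Cntnap2 and the phospholipase Pla2g5. Dkk3 (ENSMUSG00000030772) fell by 3.84 in B6, by 3.59 in 67, by 4.17 in 87 and by 3.21 in D2 on the log2 scale. Prima1 (ENSMUSG00000041669) had log2 fold changes of -3.98, -3.51, -3.91 and -4.28, Kl (ENSMUSG00000058488) of -4.13, -2.81, -3.97 and -2.43, and Cntnap2 (ENSMUSG00000039419) of -1.88, -2.79, -2.72 and -2.85. Pla2g5 (ENSMUSG00000041193) had -3.74, -6.25, -3.99 and -4.28, and was past the threshold neither in D2 with sex from the Y-linked reads (-2.39, adjusted p = 0.0791) nor in 87 without libraries 16 and 23 (adjusted p = 0.0574). The 4 comparisons share no libraries, but they share a fit with a common sex term and a pooled spread, so they are not fully independent. Sex from the Y-linked reads recodes D2 libraries only, yet it moved the counts of the other strains. They went from 2665 to 2978 in B6, from 3611 to 3372 in 67 and from 3547 to 3683 in 87. Without library 5 the count of shared genes was 197 and without library 20 it was 203. With each strain fitted on its own libraries it was 0, since edgeR then called 0 of 13910 genes in D2 (3601 unadjusted, and DESeq2 on all libraries gave 4455).

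Pairs of strains shared more changes than independent lists would. B6 and 67 had 735 genes raised and 715 lowered in common (164 and 159 for independent lists), and 4 genes changed in opposite directions. The pair 87 and D2 had 356 raised and 326 lowered in common (279 and 177), and 377 changed in opposite directions (445). Log2 fold changes correlated across genes with Pearson r of 0.57 for B6 and 67 and 0.17 for 87 and D2. Genes are not independent replicates, so no p is given for these correlations.

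In B6, CMD muscle showed higher transcripts of muscle regeneration and of the response to loss of innervation, higher matrix and oxidative phosphorylation transcripts, and lower fast fibre transcripts. Of 17 measured regeneration genes 9 rose and 1 fell (10 and 1 adjusted over the list alone), with a mean log2 fold change of 1.87 ± 2.43 (SD over genes, adjusted p = 0.00981, and adjusted p = 0.312 with an estimated correlation). Mymk went from 0.0472 ± 0.0450 to 5.01 ± 1.73 CPM (mean ± SD, n = 3). Of 18 denervation genes 10 rose and 1 fell (10 and 1 adjusted over the list alone, mean 1.56, adjusted p = 0.00851, and adjusted p = 0.309 with an estimated correlation). Of 25 fibrillar matrix genes 8 rose (8 adjusted over the list alone, mean 1.12, adjusted p = 0.0103, and adjusted p = 0.312 with an estimated correlation), and Timp1, an inhibitor of matrix proteases, rose most, by 4.97. Of 22 oxidative phosphorylation genes 17 rose (20 adjusted over the list alone, mean 0.65 ± 0.23, adjusted p = 0.00269, and adjusted p = 0.309 with an estimated correlation), among them Sdhb, from 276 ± 87.5 to 509 ± 41.3 CPM. Of 13 fast fibre genes 5 fell (6 down and 1 up adjusted over the list alone, mean -0.28, adjusted p = 0.0136, and adjusted p = 0.357 with an estimated correlation), and the fast myosin Myh4 had a log2 fold change of -1.77.

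Other lists that passed in B6 were bone and mineralisation, blood and handling, tendon and cartilage, macrophage, p53 and cell cycle genes. Of 9 bone genes 3 rose (3 adjusted over the list alone, mean 0.86, adjusted p = 0.000852, and adjusted p = 0.309 with an estimated correlation), led by Mgp, matrix Gla protein, at 3.19. Of 13 blood and handling genes 6 rose (6 adjusted over the list alone, mean 1.30, adjusted p = 0.0123, and adjusted p = 0.312 with an estimated correlation), led by the heat shock gene Hspa1b at 3.39. Of 11 tendon and cartilage genes 4 rose (6 adjusted over the list alone, mean 1.06, adjusted p = 0.0305, and adjusted p = 0.373 with an estimated correlation), among them Thbs4 at 2.58. Of 18 macrophage genes 5 rose (12 adjusted over the list alone, mean 1.09, adjusted p = 0.0344, and adjusted p = 0.385 with an estimated correlation), among them Trem2 at 2.92. Of 14 p53 and senescence genes 1 rose (4 adjusted over the list alone, mean 0.41, adjusted p = 0.0417, and adjusted p = 0.475 with an estimated correlation), Plk2 at 0.84. Of 12 cell cycle genes 2 rose (2 adjusted over the list alone, mean 1.01, adjusted p = 0.0487, and adjusted p = 0.480 with an estimated correlation), among them the replication helicase gene Mcm6 at 1.65, and the list did not pass with sex from the Y-linked reads (adjusted p = 0.0542).

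Single genes of lists that did not pass in B6 changed as well. The growth inhibitor Mstn (myostatin) fell by 2.23, the phosphorylase kinase subunit Phka1 fell by 1.62 and Dag1, dystroglycan, fell by 0.65. The stress factor Atf3 rose by 4.52, Ltbp2 by 3.39, Mfap5 by 1.67, Egr2 by 1.31, Rtp4 by 1.12, Acadl by 1.06, Esam by 0.80, and the slow fibre protein Myoz2 by 4.88. Cd3g, a T cell receptor chain, had 0 reads in WT and 34 in CMD, at least 10.4-fold higher. Ppp1r14bl rose by 6.37, while the extraocular myosin Myh13 fell by 5.20 and Fam83d fell by 3.51. In total 2665 of 14789 genes passed the threshold, 1233 raised and 1432 lowered, and 4895 had an unadjusted p under 0.05. The count was 808 without library 5 and 1305 without library 2. Without library 5 the fibrillar matrix list did not pass (adjusted p = 0.0845), and leaving out 1 B6 library ended the calls of the macrophage (2, 3 or 5), tendon (1, 3, 4 or 5), fast fibre (1, 5 or 6), p53 (2, 3, 4 or 6), cell cycle (1, 2, 3, 5 or 6) and blood (1) lists.

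In 67, CMD muscle showed a broad rise of slow fibre transcripts beside rises of regeneration, denervation, matrix and immune cell transcripts, and a fall of fast fibre and glycolytic transcripts. Of 12 slow fibre genes 11 rose (12 adjusted over the list alone, mean 5.70 ± 2.27, adjusted p = 0.00405, and adjusted p = 0.309 with an estimated correlation). The slow myosin Myh7 went from 0.943 ± 1.49 to 65.3 ± 92.9 CPM, with a large spread between the 3 CMD libraries. Of 13 fast fibre genes 9 fell and 2 rose (10 and 2 adjusted over the list alone, mean -0.23, adjusted p = 0.00165, and adjusted p = 0.309 with an estimated correlation), and the rise of Myh2, the myosin of fast oxidative fibres, was 5.54. Of 17 glycolysis and glycogen genes 11 fell (12 adjusted over the list alone, mean -0.81, adjusted p = 0.00773, and adjusted p = 0.329 with an estimated correlation), and the gluconeogenic enzyme Fbp2 fell by 2.26. Of 17 regeneration genes 11 rose (11 up and 2 down adjusted over the list alone, mean 2.33, adjusted p = 0.00337, and adjusted p = 0.309 with an estimated correlation), and the embryonic myosin Myh3 went from 0.190 ± 0.216 to 52.8 ± 26.5 CPM. Of 18 denervation genes 11 rose and 1 fell (12 and 1 adjusted over the list alone, mean 2.29, adjusted p = 0.000925, and adjusted p = 0.309 with an estimated correlation).

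Matrix and connective tissue transcripts rose together in 67. Of 25 fibrillar matrix genes 19 rose (22 adjusted over the list alone, mean 1.54 ± 1.10, adjusted p = 0.000852, and adjusted p = 0.309 with an estimated correlation), led by Timp1 at 5.71. Of 20 TGF-beta pathway genes 7 rose (7 adjusted over the list alone, mean 0.88, adjusted p = 9.19e-05, and adjusted p = 0.309 with an estimated correlation), among them Ltbp2 at 3.13. Of 15 genes of fibro-adipogenic progenitors and fibroblasts 9 rose (10 adjusted over the list alone, mean 0.77, adjusted p = 0.00414, and adjusted p = 0.320 with an estimated correlation), among them Mfap5 at 2.46. Of 24 basement membrane genes 5 rose (8 up and 4 down adjusted over the list alone, mean 0.18, adjusted p = 0.0442, and adjusted p = 0.537 with an estimated correlation), among them the collagen Col4a1 at 0.88, and the list did not pass with sex from the Y-linked reads (adjusted p = 0.0559). Of 9 bone genes 5 rose (5 adjusted over the list alone, mean 1.61, adjusted p = 4.74e-06, and adjusted p = 0.118 with an estimated correlation). Of 11 tendon and cartilage genes 5 rose (6 adjusted over the list alone, mean 1.20, adjusted p = 0.00923, and adjusted p = 0.329 with an estimated correlation), among them the lubricant proteoglycan Prg4 at 2.47.

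Immune, stress and proliferation lists also passed in 67. Of 18 macrophage genes 13 rose (15 adjusted over the list alone, mean 1.79, adjusted p = 0.00269, and adjusted p = 0.309 with an estimated correlation), led by Trem2 at 4.36. Of 11 lymphocyte genes 4 rose (4 adjusted over the list alone, mean 1.65, adjusted p = 0.00981, and adjusted p = 0.373 with an estimated correlation), and Cd3g went from 3 to 45 reads, a ratio of 15.5 (95% counting interval 4.97 to 77.8). Of 14 complement genes 7 rose (8 adjusted over the list alone, mean 1.10, adjusted p = 0.0155, and adjusted p = 0.385 with an estimated correlation), among them C3ar1 at 2.07. Of 14 p53 and senescence genes 5 rose and 1 fell (5 and 1 adjusted over the list alone, mean 1.02, adjusted p = 0.000852, and adjusted p = 0.309 with an estimated correlation), and the cell cycle inhibitor Cdkn2a rose by 4.78. Of 12 cell cycle genes 3 rose (3 adjusted over the list alone, mean 1.17, adjusted p = 0.01, and adjusted p = 0.385 with an estimated correlation), led by Mcm6 at 2.51. Of 17 integrated stress response genes 5 rose and 1 fell (7 and 1 adjusted over the list alone, mean 0.83, adjusted p = 0.0344, and adjusted p = 0.526 with an estimated correlation), led by Atf3 at 3.83. Of 13 blood and handling genes 4 rose (6 adjusted over the list alone, mean 1.24, adjusted p = 0.00651, and adjusted p = 0.320 with an estimated correlation), led by Hspa1a at 2.77.

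Oxidative phosphorylation genes did not pass as a list in 67 (4 of 22 raised, 1 adjusted over the list alone, mean 0.34, adjusted p = 0.0770), and its regulator Ppargc1a rose by 0.87. Further single genes past the threshold in 67 were Cidea (6.78), Lpl (2.30), S100a8 (4.56), Ciita (1.95), Egr2 (2.57), Mstn (-2.89), Tmem232 (-5.14) and the cadherin Cdh4 (-3.26). In total 3611 genes passed, 1973 raised and 1638 lowered, and 5475 had an unadjusted p under 0.05. The count was 2227 without library 9. All CMD libraries of 67 are female and its WT libraries are of both sexes, so this comparison leans on the sex term. With sex from the Y-linked reads, which recodes D2 libraries only, the count in 67 was 3372. The basement membrane list did not pass when any 1 of the 6 libraries of 67 was left out, nor the integrated stress list without library 7, 9 or 10, nor the complement list without library 9.

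In 87, CMD muscle showed higher denervation, regeneration and slow fibre transcripts, and its matrix transcripts fell. Of 18 denervation genes 13 rose and 1 fell (15 and 1 adjusted over the list alone, mean 2.55, adjusted p = 0.000567, and adjusted p = 0.309 with an estimated correlation). Of 17 regeneration genes 9 rose and 2 fell (9 and 2 adjusted over the list alone, mean 1.99, adjusted p = 0.0112, and adjusted p = 0.329 with an estimated correlation), among them Myh3 at 6.66. Of 12 slow fibre genes 6 rose (7 adjusted over the list alone, mean 4.37, adjusted p = 0.0122, and adjusted p = 0.329 with an estimated correlation), led by the Z-disc protein Csrp3, from 1.04 ± 0.925 to 384 ± 430 CPM, and Myoz2, from 1.99 ± 2.12 to 283 ± 219 CPM. Of 25 fibrillar matrix genes 12 fell and 1, Timp1 (3.13), rose (17 and 1 adjusted over the list alone, mean -0.72, adjusted p = 0.00571, and adjusted p = 0.320 with an estimated correlation). Of 15 genes of fibro-adipogenic progenitors and fibroblasts 8 fell (10 adjusted over the list alone, mean -0.81, adjusted p = 0.00269, and adjusted p = 0.309 with an estimated correlation), and Dpp4 fell by 2.00. Of 24 basement membrane genes 7 fell (8 adjusted over the list alone, mean -0.35, adjusted p = 0.00226, and adjusted p = 0.309 with an estimated correlation), and the nidogen Nid2 fell by 1.78. Col1a1 stood at 8.70 CPM in library 16, against 81.3 and 125 CPM in libraries 17 and 18, and without library 16 the matrix list had 8 genes lowered and 1 raised (mean -0.45, adjusted p = 0.0539).

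Mitochondrial transcripts rose in 87. All 22 oxidative phosphorylation genes rose (22 adjusted over the list alone, mean 0.97 ± 0.19, adjusted p = 0.000400, and adjusted p = 0.309 with an estimated correlation), among them the regulator Ppargc1a at 1.40. Of 14 fatty acid oxidation genes 13 rose (14 adjusted over the list alone, mean 1.70, adjusted p = 0.00213, and adjusted p = 0.309 with an estimated correlation), among them Pdk4, a brake on glucose oxidation, at 3.99 and at 2.76 without libraries 16 and 23. Of 13 fast fibre genes 6 fell and 2 rose (7 and 2 adjusted over the list alone, adjusted p = 0.0341 for a fall, and adjusted p = 0.511 with an estimated correlation). Their median was -0.49 and their mean 0.20, since Myh2 rose by 6.48. Of 14 p53 and senescence genes 7 rose and 1 fell (8 and 3 adjusted over the list alone, mean 0.70, adjusted p = 0.00269, and adjusted p = 0.309 with an estimated correlation), among them Cdkn1a at 3.14. Of 15 atrophy and autophagy genes 10 rose and 1 fell (12 and 1 adjusted over the list alone, mean 1.06, adjusted p = 0.0306, and adjusted p = 0.403 with an estimated correlation), but without library 16, which held 3815 CPM of Trim63, the mean was 0.12 (adjusted p = 0.157). Of 13 blood and handling genes 7 rose (7 adjusted over the list alone, mean 1.53, adjusted p = 0.00760, and adjusted p = 0.312 with an estimated correlation), among them Fos at 3.74. Without library 16 the blood list had 2 raised (mean 0.85, adjusted p = 0.0202), the fatty acid oxidation list 8 (mean 1.29, adjusted p = 0.0112) and the p53 list 4 (mean 0.47, adjusted p = 0.0112). Of 9 bone genes 1 rose (1 adjusted over the list alone, mean 0.49, adjusted p = 0.0344, and adjusted p = 0.484 with an estimated correlation), Spp1.

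Single genes past the threshold in 87 included the transcription factor Sox9 (2.99), Atf3 (4.75), Mcm6 (1.38) and Cidea (3.73), and Mss51 (-4.43), Cdh4 (-4.16), Phka1 (-1.62), Vwf (-1.51), Mmp9 (-1.63), C3 (-1.26), Isg15 (-1.08) and Cnp (-0.73). Several moved without libraries 16 and 23. There the autophagy gene Gabarapl1 went from 2.89 to 0.98, and Cd68 from 2.44 to 0.85 (adjusted p = 0.249). Hamp2 had 0 reads in WT and 96 in CMD, at least 33.0-fold higher, and did not pass without those libraries (adjusted p = 0.271). In total 3547 genes passed, 1910 raised and 1637 lowered, and 5419 had an unadjusted p under 0.05. The count was 1844 without library 16, 2216 without library 15 and 675 with only the 87 libraries fitted. The fast fibre list did not pass without library 14, 16 or 18 and had a mean of -0.02 without library 17, the atrophy list did not pass without library 14 or 15, and the bone list did not pass without library 13, 15 or 18.

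With sex as labelled, D2 CMD muscle showed a rise of denervation, macrophage, complement and matrix transcripts. Oxidative phosphorylation, glycolytic and fatty acid oxidation transcripts fell. The complement, matrix and fatty acid oxidation lists did not pass with sex from the Y-linked reads. Of 18 denervation genes 16 rose (17 adjusted over the list alone, mean 2.83 ± 1.66, adjusted p = 0.000789, and adjusted p = 0.309 with an estimated correlation). Of 22 oxidative phosphorylation genes 21 fell (22 adjusted over the list alone, mean -0.75 ± 0.18, adjusted p = 0.00165, and adjusted p = 0.309 with an estimated correlation), and Sdhb went from 428 ± 84.4 to 213 ± 60.1 CPM. Of the 22, 12 fell with sex from the Y-linked reads (mean -0.60, adjusted p = 0.00846). Of 17 glycolysis and glycogen genes 8 fell (10 adjusted over the list alone, mean -0.73, adjusted p = 0.00643, and adjusted p = 0.320 with an estimated correlation), and the log2 fold change of Fbp2 was -2.22 (-1.40 with sex from the Y-linked reads, adjusted p = 0.0756). Of 14 fatty acid oxidation genes 8 fell (9 adjusted over the list alone, mean -0.87, adjusted p = 0.0344, and adjusted p = 0.411 with an estimated correlation). In edgeR 0 of the 14 passed with sex from the Y-linked reads (mean -0.27, adjusted p = 0.307), and Fabp3 went from -1.59 to -0.66.

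Immune and matrix lists rose in D2 with sex as labelled. Both the amounts and some of the calls depended on the sex coding. Of 18 macrophage genes 14 rose (15 adjusted over the list alone, mean 2.14, adjusted p = 0.00190, and adjusted p = 0.309 with an estimated correlation), led by Adgre1, the F4/80 antigen, from 3 ± 0.694 to 34 ± 26.5 CPM. Only 5 rose with sex from the Y-linked reads (mean 1.14, adjusted p = 0.0292). Of 14 complement genes 13 rose (13 adjusted over the list alone, mean 2.40, adjusted p = 0.000925, and adjusted p = 0.309 with an estimated correlation), and 2 with sex from the Y-linked reads (mean 0.78, adjusted p = 0.0734). Its largest change, C7 at 8.40, became 0.26 (adjusted p = 0.817). Of 25 fibrillar matrix genes 17 rose (19 adjusted over the list alone, mean 1.45, adjusted p = 0.00115, and adjusted p = 0.309 with an estimated correlation), and with sex from the Y-linked reads 5 rose and 1 fell (mean 0.74, adjusted p = 0.0895). Of 18 interferon and antigen presentation genes 9 rose (13 adjusted over the list alone, mean 1.49, adjusted p = 0.00482, and adjusted p = 0.320 with an estimated correlation), among them H2-Eb1 at 2.74, and the list did not pass with sex from the Y-linked reads (mean 0.80, adjusted p = 0.0598). Of 11 lymphocyte genes 3 rose (5 adjusted over the list alone, mean 2.12, adjusted p = 0.00269, and adjusted p = 0.312 with an estimated correlation), led by Cd4 at 3.74, and 1 rose with sex from the Y-linked reads (mean 1.14, adjusted p = 0.0352).

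Further lists passed in D2. Of 17 regeneration genes 9 rose (9 up and 1 down adjusted over the list alone, mean 2.08, adjusted p = 0.0181, and adjusted p = 0.404 with an estimated correlation), led by Mymk at 6.64. Of 14 p53 and senescence genes 8 rose and 2 fell (9 and 2 adjusted over the list alone, mean 1.13, adjusted p = 0.000204, and adjusted p = 0.309 with an estimated correlation), among them Cdkn2a at 6.18. Of 20 TGF-beta pathway genes 4 rose (4 adjusted over the list alone, mean 0.46, adjusted p = 0.00115, and adjusted p = 0.309 with an estimated correlation). Of 9 bone genes 4 rose and 2 fell (5 and 2 adjusted over the list alone, mean 1.06, adjusted p = 0.000925, and adjusted p = 0.309 with an estimated correlation). Of 12 cell cycle genes 3 rose (6 adjusted over the list alone, mean 1.49, adjusted p = 0.00402, and adjusted p = 0.329 with an estimated correlation), and of 11 tendon genes 3 rose (6 adjusted over the list alone, mean 1.41, adjusted p = 0.0114, and adjusted p = 0.373 with an estimated correlation). Of 15 genes of fibro-adipogenic progenitors and fibroblasts 4 rose (4 adjusted over the list alone, mean 0.56, adjusted p = 0.0201, and adjusted p = 0.475 with an estimated correlation), among them Cxcl14 at 1.30. Of 24 basement membrane genes 7 rose (10 up and 2 down adjusted over the list alone, mean 0.17, adjusted p = 0.0259, and adjusted p = 0.530 with an estimated correlation), and of 13 blood and handling genes 2 rose (2 adjusted over the list alone, mean 0.90, adjusted p = 0.0348, and adjusted p = 0.502 with an estimated correlation). With sex from the Y-linked reads the fibro-adipogenic (adjusted p = 0.652), basement membrane (adjusted p = 0.243) and blood (adjusted p = 0.0689) lists did not pass. The other lists of this paragraph passed, with means of 2.27 for regeneration, 1.15 for p53, 0.37 for TGF-beta, 0.84 for bone, 1.12 for cell cycle and 1.20 for tendon, as did denervation (3.29) and glycolysis (-0.82).

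Among the largest single increases in D2 were Cntn2, a contactin of nerve axons, from 0.0662 ± 0.0412 to 42.3 ± 33.5 CPM, Jchain, the joining chain of secreted antibodies (9.14), and the keratin Krt8 (7.73). Timp1 rose by 4.30, Cfd by 4.24, Csf3r by 2.96, Mbp by 1.87 and Junb by 1.84. The myokine Ostn had a log2 fold change of -4.79 and Mstn of -1.69. Genes past the threshold with the label but not with sex from the Y-linked reads included Ltbp2 (2.70 and 1.25), Tnmd (2.14 and 0.58), Acp5 (3.69 and 2.05), Mki67 (2.89 and 1.79), Nid2 (1.01 and 0.12), Fgf21 (3.35 and 2.59), Lrrc52 (-4.30 and -2.55), BC048679 (-4.58 and -2.47), Flt1 (-0.94 and -0.56) and Atp2a1 (-0.68 and -0.56). In total 3754 genes passed, 2157 raised and 1597 lowered, and 5764 had an unadjusted p under 0.05. With sex from the Y-linked reads the count was 2482, of which 1860 also passed with the label in the same direction, and without library 20 it was 2097. It was 941 without libraries 16 and 23 and with sex from the Y-linked reads. In that setting all D2 WT libraries are female and all D2 CMD libraries male. Sex and genotype cannot be told apart within D2 there, and the sex term comes from the other strains. The same holds by the label without library 20, where D2 WT is all male and D2 CMD all female. With only the D2 libraries edgeR gave 0 of 13910 (3601 unadjusted), and DESeq2 on all libraries gave 4455. Leaving out 1 D2 library ended the calls of the regeneration (20 or 23), fibro-adipogenic (20, 21 or 23), tendon (20), fatty acid oxidation (21, 23 or 24), basement membrane (19, 20, 21 or 24) and blood (20, 21, 22 or 23) lists.

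**Figure D4:**
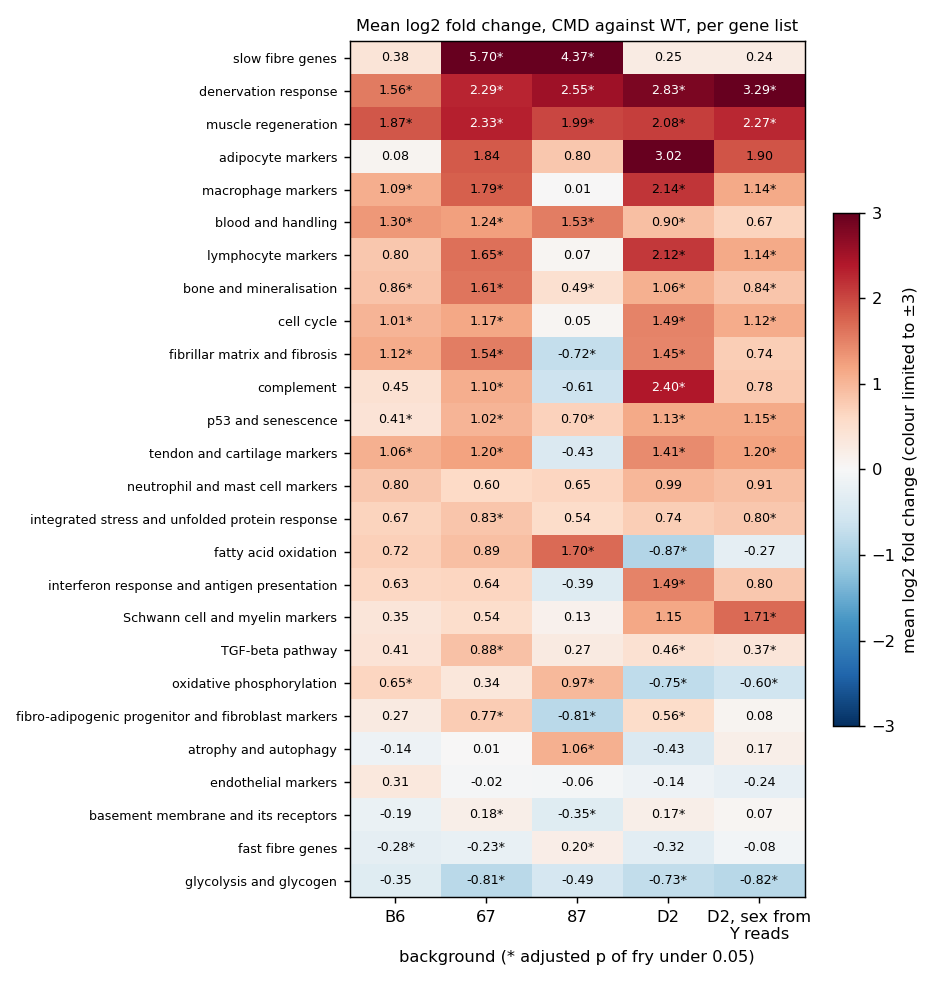
Mean log2 fold change of CMD against WT for the members of 26 gene lists in each background, with D2 also fitted with sex from the Y-linked reads, and an asterisk where the adjusted p of fry is under 0.05. Oxidative phosphorylation stands at 0.65, 0.34 and 0.97 in B6, 67 and 87 and at -0.75 in D2, and fibrillar matrix is negative in 87 alone (-0.72).

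Some lists passed in no strain. Adipocyte transcripts had means of 0.08, 1.84, 0.80 and 3.02 in B6, 67, 87 and D2, with adjusted p = 0.0871 in D2, where Adipoq stood at 169 and 197 CPM in libraries 22 and 23 and at 4.54 CPM in library 24. Schwann cell and myelin transcripts had means of 0.35, 0.54, 0.13 and 1.15, and in D2 10 of 14 rose with sex from the Y-linked reads (mean 1.71, adjusted p = 0.00813, and adjusted p = 0.339 with an estimated correlation). Endothelial transcripts had means of 0.31, -0.02, -0.06 and -0.14, and neutrophil and mast cell transcripts of 0.80, 0.60, 0.65 and 0.99. Of 104 tests of a list in a strain 60 passed, and 0 passed in camera with an estimated correlation, where 14 had an unadjusted p under 0.05.

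Whether the CMD response differs between backgrounds was tested directly with the interaction terms. D2 stood apart in mitochondrial transcripts and 87 in matrix transcripts. Mdh1, the cytosolic malate dehydrogenase, rose in B6, 67 and 87 by log2 fold changes of 1.10, 0.88 and 1.43 and fell in D2 (-1.13; F test, adjusted p = 0.00149). The same contrast was seen for the respiratory chain genes Sdhb (1.02, 0.65, 1.32 and -1.23, adjusted p = 0.00166) and Cox5b (0.89, 0.54, 1.12 and -0.60, adjusted p = 0.00166) and for the mitochondrial thioredoxin Txn2 (0.81, 0.45, 0.99 and -0.33, adjusted p = 0.00166). The phosphatase gene Dusp18 changed by 1.96, 3.50, 3.82 and -1.37 (adjusted p = 0.00149). Spon2, a matrix protein, fell in 87 (-2.19) and rose in B6, 67 and D2 (1.99, 1.63 and 1.28, adjusted p = 0.00166).

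Further genes stood among the 12 with the smallest F test p. Osbpl3, an oxysterol-binding protein, rose by 2.74, 3.52 and 2.97 in B6, 67 and 87 and stood at 0.28 in D2, where WT already held 15.5 ± 3.61 CPM against 1.37 ± 0.267 in B6 WT (adjusted p = 0.000543). The transporter Slc47a1 had log2 fold changes of 2.13, 1.43, 1.96 and -0.27 (adjusted p = 0.00166), and D2 WT stood above B6 WT by 1.33. Fggy, a carbohydrate kinase, went from 0.0978 ± 0.0924 to 9.10 ± 5.32 CPM in D2 and was 6.74 ± 1.36 and 6.61 ± 0.625 CPM in B6 WT and CMD (adjusted p = 0.000543). Sh3pxd2a changed by -0.57, 0.76, -0.42 and 1.44 (adjusted p = 0.00149), and Nmnat1, an enzyme of NAD synthesis, by 0.30, -0.37, 0.22 and -1.01 (adjusted p = 0.00166). Ddx3y (adjusted p = 0.00149) is Y-linked and had adjusted p = 0.403 with sex from the Y-linked reads, where the other 11 passed. In total 1555 genes passed the F test and 4273 had an unadjusted p under 0.05. With sex from the Y-linked reads the count was 763, without library 13 it was 815 and without library 21 it was 933.

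The list tests located these differences. Oxidative phosphorylation genes differed between D2 and B6 by -1.40 ± 0.28 (mean over 22 genes, 21 lower, adjusted p = 0.000540, and adjusted p = 0.123 with an estimated correlation), between D2 and 67 by -1.09 (adjusted p = 0.00207, and adjusted p = 0.143 with an estimated correlation) and between D2 and 87 by -1.72 (adjusted p = 0.000213, and adjusted p = 0.123 with an estimated correlation). The difference between D2 and B6 was -1.24 (adjusted p = 0.00154) with sex from the Y-linked reads. Fibrillar matrix genes in 87 differed by -1.84 from B6 (adjusted p = 0.00156, and adjusted p = 0.0705 with an estimated correlation), by -2.26 from 67 (17 of 25 lower, adjusted p = 0.000420, and adjusted p = 0.0705 with an estimated correlation), and D2 differed from 87 by 2.17 (adjusted p = 0.000540, and adjusted p = 0.143 with an estimated correlation), or by 1.42 with sex from the Y-linked reads (adjusted p = 0.0145). Fibro-adipogenic and fibroblast genes in 87 differed by -1.08 from B6 and by -1.59 from 67 (adjusted p = 0.00997 and 0.000748, and adjusted p = 0.143 and 0.111 with an estimated correlation). Slow fibre genes differed between D2 and 67 by -5.45 (adjusted p = 0.0374, and adjusted p = 0.246 with an estimated correlation), but not past the threshold with sex from the Y-linked reads (adjusted p = 0.106), nor without library 7, 8, 9, 10, 12, 19, 21, 22 or 24. Of 156 tests of differences 30 passed, and 0 passed in camera with an estimated correlation, where 23 had an unadjusted p under 0.05.

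**Figure D5:**
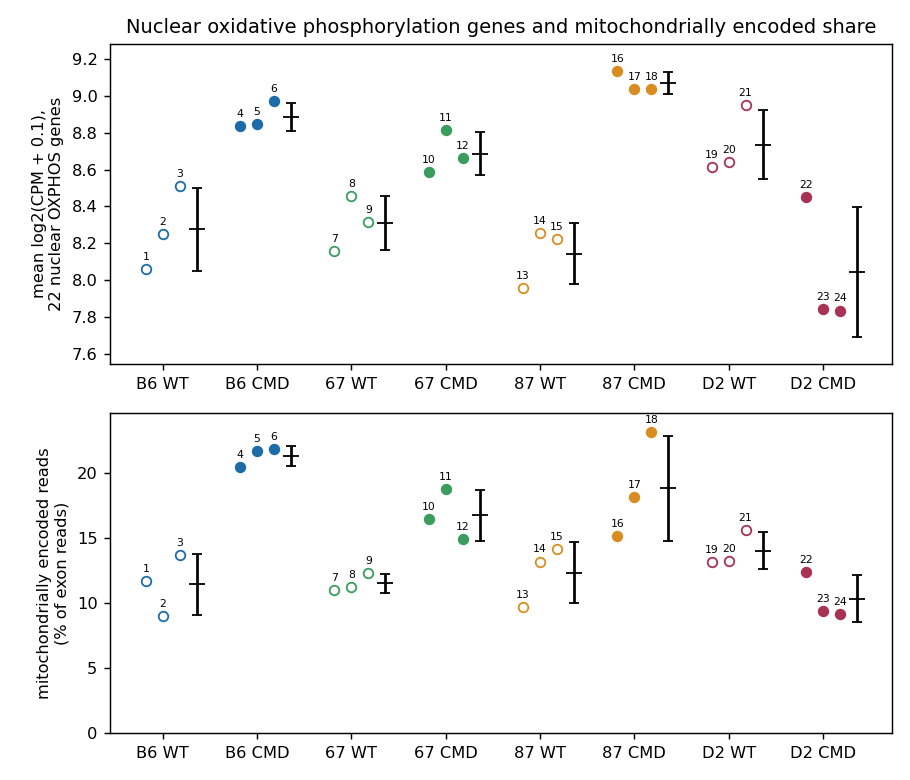
Upper panel, mean log2(CPM + 0.1) of 22 nuclear oxidative phosphorylation genes per library; lower panel, mitochondrially encoded reads as a percentage of exon reads, with the mean and SD of each group of 3 at the right of its points. Both measures are higher in CMD than WT libraries in B6, 67 and 87, and lower in D2.

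By pair of strains, 1 gene differed in effect between 67 and B6, 8 between 87 and B6, 306 between 87 and 67, 445 between D2 and 67, 838 between D2 and B6, and 2575 between D2 and 87. The unadjusted counts under 0.05 were 1458, 2145, 3124, 2437, 3154 and 4816. D2 and B6 are the parents of the BXD strains and were compared in detail. Relative to B6, the effect in D2 was higher for Fggy (7.10 ± 0.73 SE, adjusted p = 0.000136), Sh3pxd2a (2.01, adjusted p = 0.000732) and Ltbp1, a latent TGF-beta binding protein (1.92, adjusted p = 0.00135, but 1.12 and adjusted p = 0.0593 with sex from the Y-linked reads). It was lower for Slc47a1 (-2.40, adjusted p = 0.000865), Nmnat1 (-1.30, adjusted p = 0.000959), Txn2 (-1.14, adjusted p = 0.00160), Mdh1 (-2.23, adjusted p = 0.00160), the succinate dehydrogenase gene Sdhc (-1.48, adjusted p = 0.00160) and Osbpl3 (-2.46, adjusted p = 0.00160). Ddx3y, Eif2s3y and Kdm5d are Y-linked and also stood among the 6 raised with the smallest p, but not past the threshold with sex from the Y-linked reads. Of the 838 genes 332 were higher and 506 lower. With sex from the Y-linked reads the count was 536, of which 443 also passed with the label in the same direction, and it was 435 without library 1, 538 without library 6 and 546 without library 21.

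Baseline differences were asked among the 4 WT groups. The genes with the smallest p between D2 WT and B6 WT are given here. Sfi1, a centrosome protein, stood at 72.8 ± 4.19 CPM in D2 WT and 6.09 ± 0.616 in B6 WT (log2 difference 3.51, adjusted p = 6.93e-09). Kbtbd12 (2.38), Hyi (2.61), Hddc3 (1.85) and Osbpl3 (3.67) were also higher in D2 WT. Cox5b-ps stood at 28.8 ± 3.04 against 0.444 ± 0.166 CPM (6.24, adjusted p = 7.10e-09), but it is a pseudogene of Cox5b and reads of the parent gene can be assigned to it. Unc5a, a netrin receptor, stood at 1.64 ± 0.138 CPM in D2 WT and 31.4 ± 6.99 in B6 WT (-4.17, adjusted p = 6.93e-09). The glutamate transporter Slc1a2 (-7.26), the securin Pttg1 (-4.78), Zfp33b (-4.79) and Fggy (-6.28) were also lower in D2 WT. Snap25, a synaptic protein, had 358 reads in B6 WT and 0 in D2 WT, at least 151-fold lower with a floor of 3 reads over the group.

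Of 14789 genes 1339 differed among the 4 WT groups (3529 with an unadjusted p under 0.05), and 1124 between D2 WT and B6 WT (438 higher and 686 lower in D2; 3019 unadjusted). The first count was 682, 874 and 639 without libraries 19, 20 and 21, and the second was 633, 698 and 685 without libraries 1, 2 and 21. Among the genes lower in D2 WT were 15 of 24 transcripts of brain neurons on a list written after this was seen, and 0 of the 24 were higher by edgeR. The mean log2(CPM + 0.1) of these 24 genes was 0.19 to 1.29 in the 18 B6, 67 and 87 libraries and -1.44 to -0.73 in the 6 D2 libraries. Over the 18 libraries, 134 genes that differ between D2 WT and B6 WT by at least 2 on the log2 scale correlated above 0.7 with this mean. Entry of brain RNA into the 18 libraries is left open below. The WT counts can therefore hold genes that do not differ by strain.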

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

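The tests of the sex labels, the neuronal transcripts and oxidative phosphorylation were chosen only after those results were seen.

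Differences between the backgrounds were picked out because the CMD effect differed between groups. By the F test over the 4 strains 1555 genes differed, and by pair 1 (67 minus B6), 8 (87 minus B6), 838 (D2 minus B6), 306 (87 minus 67), 445 (D2 minus 67) and 2575 (D2 minus 87). The genes were Fggy and Osbpl3 (adjusted p = 0.000543 each), Sh3pxd2a, Ddx3y, Mdh1 and Dusp18 (0.00149 each), Txn2, Slc47a1, Nmnat1, Cox5b, Spon2 and Sdhb (0.00166 each) and Lama2 (0.0119).

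Gene lists were picked out for the same reason, each by its largest mean log2 difference. Between 87 and 67 these were -0.53 for basement membrane, -0.61 for TGF-beta, -1.12 for bone, -2.26 for fibrillar matrix and -1.59 for fibro-adipogenic genes. Between D2 and 87 they were -1.72 for oxidative phosphorylation, -2.57 for fatty acid oxidation, 2.13 for macrophage, 3.02 for complement, 2.05 for lymphocyte, 1.88 for interferon and 1.44 for cell cycle genes. With sex from the Y-linked reads the D2 minus 87 values were -1.56, -1.96, 1.18, 1.40, 1.10, 1.28 and 1.10 in that order, and the macrophage, lymphocyte and cell cycle differences did not pass (adjusted p = 0.0931, 0.111 and 0.0931). Without library 16 the macrophage (2.04, adjusted p = 0.0618), lymphocyte (1.94, 0.0923), interferon (1.27, 0.0923) and cell cycle (0.77, 0.217) differences did not pass either. Leaving out library 13 also ended the macrophage call, and leaving out 15, 19, 20, 21 or 24 the cell cycle call. In camera 0 of 156 differences passed (23 unadjusted), where fry gave 30. Slow fibre genes had -5.45 (D2 minus 67) and p53 genes 0.72 (D2 minus B6). The slow fibre difference did not pass without library 7, 8, 9, 10, 12, 19, 21, 22 or 24, nor without library 16 of 87 (adjusted p = 0.0588). The p53 difference did not pass without library 1, 3, 5, 19, 21, 23 or 24, with a p53 mean of 0.36 without library 1.

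The Y-linked reads of 4 of 6 D2 libraries went against their labels. The sex read from 6 of 6 D2 libraries equals the label in the same place of the other D2 group. This uses the same reads and labels that raised the question, so it is no independent test, and whether the sex entries were exchanged is left open. An exchange of the genotype labels is argued against by direction, since 83.8% of 896 genes changed the same way in B6, 67 and 87 kept that direction in D2 (90.3% with sex from the Y-linked reads).

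Transcripts of neurons were present in B6, 67 and 87 and low in D2. Less nerve in the D2 samples is argued against by Schwann cell genes, which differed between D2 WT and B6 WT by 0.72 ± 0.617 (mean ± SD, 14 genes). Entry of brain RNA was left open by a median pairwise Spearman correlation of 0.452 over 276 pairs of genes. Strain alleles were left open too, since 4.17% of the genes in 67 WT and 16.7% in 87 WT were nearer D2 than B6.

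Oxidative phosphorylation genes rose in B6 and 87 CMD and fell in D2 CMD. Wrong sex labels are argued against, because the difference between D2 and B6 was -1.24 with sex from the Y-linked reads (adjusted p = 0.00154). Dilution of fibre RNA by other cells is left open by the log2 ratio to 22 sarcomere genes, which was -3.58 ± 0.24 in D2 WT and -3.98 ± 0.26 in D2 CMD. The highest D2 CMD library (22, -3.81) lay just below the lowest D2 WT library (20, -3.79). The ratio does not isolate dilution, since sarcomere genes also changed in CMD of other strains. Their mean log2(CPM + 0.1) was 12.66 to 12.72 in 67 WT and 11.86 to 12.03 in 67 CMD. The D2 change of the ratio, -0.40, is small beside 1.25, 1.11 and 1.43 in B6, 67 and 87, and with 3 against 3 libraries no exact p can be below 0.1.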

How the results depend on the processing

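The alternatives with sex from Y-linked reads, with unique reads, and without libraries 16 and 23 were chosen only after results were seen. Where a value moved below, the cause was not tested, apart from settings that hold fewer libraries or a stricter threshold. Among named genes past the threshold, 1787 comparisons with an alternative kept their side and direction, 235 lost the threshold and 2 turned direction, and with 1 library left out 1279 kept and 131 lost it. Among called lists these were 425, 173 and 2, and with 1 library left out 301, 58 and 1. Among called list differences between strains they were 168, 100 and 2, and with 1 library left out 291 kept and 69 lost the threshold. A 2-fold difference in effect among strains was recovered in 16% of simulated genes, so small differences are missed.

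With a log2 fold change of at least 1 the counts were 948 in B6, 1715 in 67, 1516 in 87, 1914 in D2 and 157 shared. With the 15 females they were 852 in B6, 1094 in D2, 132 shared, 63 among WT and 169 for D2 WT against B6 WT. For the effect in D2 against B6 the females gave 0 of 15263 in edgeR (1609 unadjusted), where DESeq2 on all libraries gave 1445. Among the females B6 CMD held library 5 alone, 87 CMD library 16 alone and D2 WT library 20 alone. Libraries 22 and 24 of D2 CMD, taken as female by label, held 4927 and 4858 Y-linked reads. The counts in females therefore rest on groups of 1 library and cannot show whether the calls hold within a sex. With only the libraries compared the counts were 675 in 87, 0 of 13910 in D2 in edgeR (3601 unadjusted, where DESeq2 on all libraries gave 4455), 0 shared, 19 for the effect in D2 against B6, 2198 among WT and 637 for D2 WT against B6 WT, and 7 lists passed. In camera 0 of 104 lists passed (14 unadjusted), where fry gave 60. DESeq2 gave 2903 for the F test and 2257 among WT. Without a sex term the F test gave 690 and D2 against B6 536, and for Lama2 the F test gave 0.0131 before adjustment (adjusted p = 0.119).

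With sex from the Y-linked reads the counts were 2482 in D2, 763 for the F test and 536 for D2 against B6. Without libraries 16 and 23 they were 1932 in 87, 1406 for D2 against B6 and 2011 among WT. Without both and with sex from the Y-linked reads they were 2168 in 87, 941 in D2, 690 for the F test and 232 shared, and for Lama2 the F test gave 0.00779 before adjustment (adjusted p = 0.0896). There the means of fibro-adipogenic genes (-0.050), C7 (-0.57) and Lama4 (-0.086) in D2 turned negative. By these reads D2 WT is then all female and D2 CMD all male. These D2 values therefore cannot be told apart from sex within D2. Direction also turned for neutrophil and mast cell genes in 87 with only the libraries compared (-0.32), for fast fibre (-0.34) and cell cycle (-2.10) genes in 87 in females, for fast fibre genes in 87 without library 17 (-0.024, against 0.44 without library 16), and for bone genes, D2 minus 67, without a filter (0.25) and in females (0.031). Among the females 87 CMD held library 16 alone and D2 WT library 20 alone, so the turns in females rest on single libraries.

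With 1 library left out the counts ran from 808 (without 5) to 2131 (4) in B6, 2227 (9) to 2714 (8) in 67, 1844 (16) to 4023 (17) in 87, 2097 (20) to 3969 (22) in D2, 197 (5) to 479 (22) shared, 815 (13) to 2236 (18) for the F test, 435 (1) to 1027 (23) for D2 against B6, 639 (21) to 1278 (1) among WT, and 633 (1) to 1027 (3) for D2 WT against B6 WT. Each of these ranges covers the libraries of the groups that its count compares. Unless stated, the left-out libraries named above belong to those groups too. Libraries of other groups share the fit and can move a count further. Without library 16 of 87 the counts were 3634 in B6, 4498 in 67, 4715 in D2, 1180 for D2 against B6 and 1489 for D2 WT against B6 WT. Lists passing ran from 53 (20) to 62 (22). Lama2 ran from -1.34 to -0.94 in B6, -0.00 to 0.35 in 67, -1.08 to -0.98 in 87 and -0.33 to -0.02 in D2, with F test p from 4.06e-05 to 0.00203.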

Other observations

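The tests of the genes near Lama2 were chosen only after the Lama2 result was seen, and those of chance groupings before. The parental block test was set before its result was seen, but the genes left out of it as neuronal were chosen after those transcripts were seen.

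Library 16 (87 CMD) held high levels of stress and atrophy transcripts beside its metallothioneins. Fkbp5 stood at 273 CPM against 14.6 and 16.2 in libraries 17 and 18, Ddit4 at 315 against 12.2 and 10.6, Cebpd at 178 against 9.02 and 7.71, and Fbxo32 at 3036 against 371 and 380. In library 23 (D2 CMD) the myelin transcript Mbp stood at 98 CPM, against 20.7 and 53.8 in libraries 22 and 24.

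Mitochondrially encoded transcripts of 13 genes made up 11.5 ± 2.34% of exon reads in B6 WT and 21.4 ± 0.755% in B6 CMD (mean ± SD, n = 3). The shares were 11.5 ± 0.703% and 16.8 ± 1.94% in 67, 12.3 ± 2.36% and 18.8 ± 4.06% in 87, and 14 ± 1.4% and 10.3 ± 1.82% in D2. These were not tested.

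Flanking DNA carried along with the mutation was tested with the 150 genes nearest Lama2. No excess of calls passed the test, with odds ratios of 1.09 in B6, 1.21 in 67, 1.04 in 87 and 1.11 in D2 (Fisher exact p = 0.669, 0.295, 0.848 and 0.572). This is a negative result.

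Parental blocks were tested with 339 autosomal genes that differ between B6 WT and D2 WT past the threshold and by at least 2 on the log2 scale. Before that, 134 genes that followed the neuronal transcripts (correlation above 0.7) were left out. In 67 WT 16.8% and in 87 WT 18.6% were nearer D2. Of 320 neighbouring pairs 77.2% had the same parent in 67, against 71.9% with permuted positions (permutation p = 0.001), and 76.2% in 87 against 69.6% (permutation p = 4e-04). This is a positive result for blocks of each parent, which BXD strains carry, but the margin is small. The highest permuted shares were 78.1% in 67 and 76.2% in 87. Most of the genes stood nearer B6 in both strains, and the reason was not tested.

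Chance groupings were compared with the real ones. Of 100 regroupings, the real one included, 1 gave as many shared genes as the real 383 (highest other 0), 1 as many in the F test as 1555 (35), 3 as many for D2 against B6 as 838 (861), and 1 as many among WT as 1339 (979). With 10 splits of 3 against 3 there are too few for a share under 0.05. In each of these 1 split, the real one, gave as many, with 2665 in B6 (highest other 1), 3611 in 67 (0), 3547 in 87 (2), 3754 in D2 (155) and 1124 for D2 WT against B6 WT (1).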
